A study of Mus musculus with 6 samples.

How the data were processed

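RNA was measured in 6 libraries, 3 of mammary gland and 3 of mammary tumour, from 5-month-old female FVB/NJ mice. Per the labels, tissue was flash frozen, total RNA was extracted with Trizol and a column kit, genomic DNA was removed and libraries were made with Illumina protocols. Read length, strandedness and the number of reads are not given in the sources used here. The processing notes name HISAT2, StringTie and the mouse build mm10, without versions and without saying which step each did. The deposited table gives 1 value per gene symbol and library for 24421 symbols, of which 6247 were at 0 in all 6 libraries. Its header names no unit. The deposited values were taken as FPKM, normalised by the authors for transcript length and for the mapped fragments of each library, because they were not whole, never negative and summed to different totals in each library, between 486080 and 582996. The gene annotation used by the authors is not given in the sources used here. Symbols were placed on the genome with GENCODE M21 for GRCm38, the build also called mm10, where 95.5% of the symbols matched exactly 1 gene.

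The samples fall into 2 groups, mammary gland and mammary tumour, each numbered 1 to 3 in the order of the labels. The labels do not pair glands with tumours, and the deviations of log2 values from their group means had r = -0.054, -0.118 and -0.124 between libraries of the same number, across genes, which are not independent replicates. The numbers were therefore not used as pairs. The comparison was tumour minus gland. Genes with a mean of at least 1 FPKM over the 6 libraries (13364 genes) were tested on log2(FPKM + 1) with the moderated test of limma 3.58.1 with a mean-variance trend in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. FPKM values carry no counts, so the counting error of single values did not enter the model.

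Gene lists for cell types, pathways and complexes, 41 in all, were tested where at least 5 members were measured, which held for 40, with camera of limma at a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were run beside it. Members of each list were counted at the threshold over all tested genes and again with the adjustment over the list alone. The peptide loading complex genes, Rb1, Trp53 and Trim71 also had a 2-sided exact permutation test of the difference in mean log2(FPKM + 1) over the 20 arrangements of 3 against 3, for which the smallest p is 0.1. The groups, the tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined.

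The rule named the 10 largest rises and the 10 largest falls among genes past the threshold. These needed separate groups and a mean of at least 5 FPKM in the higher group, and 153 genes with predicted or segment names were left out. It also named, in each list, up to 4 members past the threshold with the smallest p and up to 2 that did not pass with the highest mean, and the peptide loading complex genes, Rb1, Trp53 and Trim71. The list members given in the text are a subset of those the rule gives, taken in its order, and a few that it gives are not reported here. Other genes are given with the words that they were chosen after their values were seen, apart from the neighbours of a gene that overlap it.

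The alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, quantile normalization, median-of-ratios scaling, the replicate number as a block, each library left out in turn, array weights, a fold change of at least 2, fry, an estimated correlation, and the study genes relative to the luminal epithelium list or to Ptprc. The alternatives chosen after seeing the data were a common sum per library, tumours 1 and 2 averaged as 1 sample, glands 1 and 3 left out together, removal of a loess trend (span 0.5) of each library's log2 deviations from the gene means on GC content and gene length, and array weights estimated gene by gene. The last was added because the default estimate of array weights did not converge. Where a fit left a group with 1 library, that library was assumed to vary like the others.

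Relative depth was estimated from the steps between values under 0.3 FPKM of the same gene in different libraries. Of 7449 such pairs, 578 lay on the step ratio of their libraries within 0.02 log2 units. The ratios were chosen to give the most such pairs, so the mean of 83.5 pairs for random ratios is no test of them. On simulated data made from these libraries with 200 changed genes, the gene test recovered 54% of genes changed 2-fold and 91% of genes changed 4-fold. There, 6.45% of its calls were unchanged genes, and with no gene changed it made 0 calls. With 200 of 13364 genes changed there, against 6023 called in the data, these rates may not carry over. The list test recovered 2 of 2 shifted lists and called 0 others. Genes were drawn independently there, so the simulation does not show how correlation between genes affects list calls. Runs of neighbouring genes along the chromosomes were scanned by their median log2 fold change. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The human LINK-A transcript was not analysed here.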

Results

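The series compared RNA from mammary tumours with RNA from mammary glands of 5-month-old female FVB/NJ mice that carry a transgene for LINK-A, a long non-coding RNA found in human breast tumours. The tumours came from mice in which the transgene was under the mouse mammary tumour virus (MMTV) promoter, which is active in mammary epithelium. The label of the gland donors names the transgene and not MMTV. There were 3 mammary gland and 3 mammary tumour libraries of total RNA, and 24421 genes had a value in each, in FPKM, a fragment count scaled to transcript length and to the mapped fragments of the library. The FPKM values summed to between 495986 and 510957 per gland library and between 486080 and 582996 per tumour library. Between 16218 and 16643 genes lay above 0 FPKM in the glands and between 15000 and 15749 in the tumours. Total read counts were not given, so the absolute depth was unknown. From the steps between low values, the shallowest library was tumour 1 and the deepest gland 3, at 1.88 times its depth, and the other libraries lay between 1.43 and 1.58 times that of tumour 1. These are rough estimates, and 16 pairs of low values lay on the ratio of gland 3 and tumour 1. The labels name the libraries of a group as separate samples without saying that they came from separate animals, so the p-values measure only the spread between these samples. LINK-A itself was not analysed here.

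The comparison of tumour with gland asked which transcripts differ between the tumour tissue and mammary gland of the same age. The donor labels differed between the groups along with the tissue. A difference in genotype, if there was one, thus cannot be told apart from the difference in tissue. Acute phase serum amyloid genes and the defence genes S100a8 and Ltf rose in the tumours, and adipocyte genes fell. Saa2 rose from 2.43 ± 1.64 FPKM in the glands to 3561 ± 1938 FPKM in the tumours (mean ± SD, n = 3 each), Saa1 from 6.87 ± 1.91 to 3240.1 ± 1762 and Saa3 from 4.17 ± 2.20 to 1555 ± 1048. These were log2 fold changes of 9.94 (SE 0.51, adjusted p = 3.4e-05), 8.52 (SE 0.48) and 8.04 (SE 0.65), on the log2(FPKM + 1) scale used for every fold change given here, which understates the changes of low genes. The 3 genes lie close together on chromosome 7 of mm10, from 46711998 to 46754313, and Saa1 and Saa2 are near-identical copies, so the division of reads between them is uncertain. Tumour 3 held the lowest tumour value of each, at 1518, 1291 and 472 FPKM, and without it Saa3 stood at 8.74.

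The symbol a, which names the agouti gene, a secreted regulator of coat pigment, stood at 0, 0.698 and 0 FPKM in glands 1 to 3 and at 793, 702 and 836 FPKM in the tumours, a log2 fold change of 9.34 (SE 0.22, adjusted p = 4.8e-06). Its annotated span (chromosome 2, 154791402 to 155051012, mm10) overlaps Raly on the same strand and Eif2s2 on the other, so that its level is uncertain. Raly itself stood at 103 ± 5.28 FPKM in the glands and 132 ± 3.51 in the tumours, and Eif2s2 at 48.8 ± 2.81 and 61.3 ± 3.32. Both overlapping genes were thus measured in the glands, where a stood near 0, and rose far less than a. This argues against their reads as the whole source of its rise. The kallikrein peptidase gene Klk10 rose by 7.11 (SE 0.50, adjusted p = 1.1e-04) from 0.563 ± 0.310 FPKM to 135, 139 and 510 FPKM in tumours 1 to 3, or by 6.49 without tumour 3. S100a8, one part of neutrophil calprotectin, rose by 5.70 (SE 0.86, adjusted p = 0.00204) from 21.6 ± 7.003 FPKM to 3100, 1833 and 259 FPKM in tumours 1 to 3, or by 4.98 without tumour 1 and 6.77 without tumour 3. Its call was lost without glands 1 and 3 (6.18, adjusted p = 0.0821, range 3.9e-07 to 0.0821 over its alternatives). Ltf, the iron-binding lactoferrin of milk and neutrophils, rose by 5.45 (SE 0.11, adjusted p = 2.8e-06) from 40.3 ± 1.81 to 1809 ± 177 FPKM. Apol9a, an interferon-induced apolipoprotein L gene with a near-identical neighbour, rose by 5.33 (SE 0.27) and the chloride channel gene Clic6 by 5.02 (SE 0.53). Clic6 stood at 22.9, 30.4 and 109 FPKM in tumours 1 to 3, with a log2 fold change of 4.35 without tumour 3. Its call was lost without glands 1 and 3 (4.99, adjusted p = 0.0509, range 1.7e-07 to 0.0509 over its alternatives). The ubiquitin ligase gene Rnf183 was listed at 0 in all 3 glands and at 26.96, 31.5 and 37.8 FPKM in the tumours (adjusted p = 8.6e-06).

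The 10 largest falls included genes of fat cells. Retn, which encodes the adipokine resistin, fell from 466 ± 69.7 to 1.89 ± 2.03 FPKM (log2 fold change -7.61, SE 0.53, adjusted p = 1.0e-04). The retinol carrier gene Rbp4 fell from 203 ± 6.16 to 1.41 ± 1.22 (-6.58, SE 0.43) and Adipoq, which encodes adiponectin, from 669 ± 7.07 to 9.91 ± 7.24 (-6.31, SE 0.63). The lipid droplet gene Plin1 fell from 261 ± 18.3 to 3.03 ± 2.10 (-6.19, SE 0.42), the triglyceride synthesis gene Dgat2 from 432 ± 23.2 to 4.87 ± 0.314 (-6.21, SE 0.10) and the carbonic anhydrase gene Car3 from 3903 ± 381 to 45.9 ± 33.6 (-6.86, SE 0.76). Without tumour 3 the log2 fold changes were -6.99 for Retn, -5.49 for Adipoq and -5.88 for Car3. The call of Car3 was lost without glands 1 and 3 (-6.99, adjusted p = 0.0536, range 2.8e-07 to 0.0536 over its alternatives). Cox8b, the cytochrome oxidase subunit of brown fat and muscle, fell by 6.78 (SE 0.46, adjusted p = 9.4e-05). Rspo1, an R-spondin that amplifies Wnt signalling in the mammary epithelium, fell from 102 ± 9.27 to 0.461 ± 0.320 FPKM (-6.16, SE 0.18, adjusted p = 7.7e-06). Calca, the calcitonin gene, stood at 187, 194 and 224 FPKM in glands 1 to 3 and was listed at 0 in all 3 tumours (adjusted p = 5.7e-07). The alpha globin gene Hba-a2, a near-identical copy of Hba-a1, passed the test at -7.66 (SE 2.12, adjusted p = 0.0241) with tumour values of 651, 1.16 and 0.995 FPKM. Hba-a1 stood at 12.8, 598 and 376 FPKM in the same tumours and did not pass (0.23, adjusted p = 0.908), and the division of reads between the copies is uncertain. Without 1 library the log2 fold change of Hba-a1 lay between -0.78 and 1.93, and it passed with array weights (adjusted p = 0.00282, range 0.00282 to 0.993 over its alternatives). The call of Hba-a2 was lost without gland 1 (adjusted p = 0.0559), gland 2 (adjusted p = 0.0669), gland 3 (adjusted p = 0.0658), tumour 2 (adjusted p = 0.0789), tumour 3 (adjusted p = 0.0537) or glands 1 and 3 (adjusted p = 0.244, range 1.2e-05 to 0.244 over its alternatives). The log2 fold change of Hba-a2 was -10.43 without tumour 1, -6.31 without tumour 2 and -6.25 without tumour 3.

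**Figure D1:**
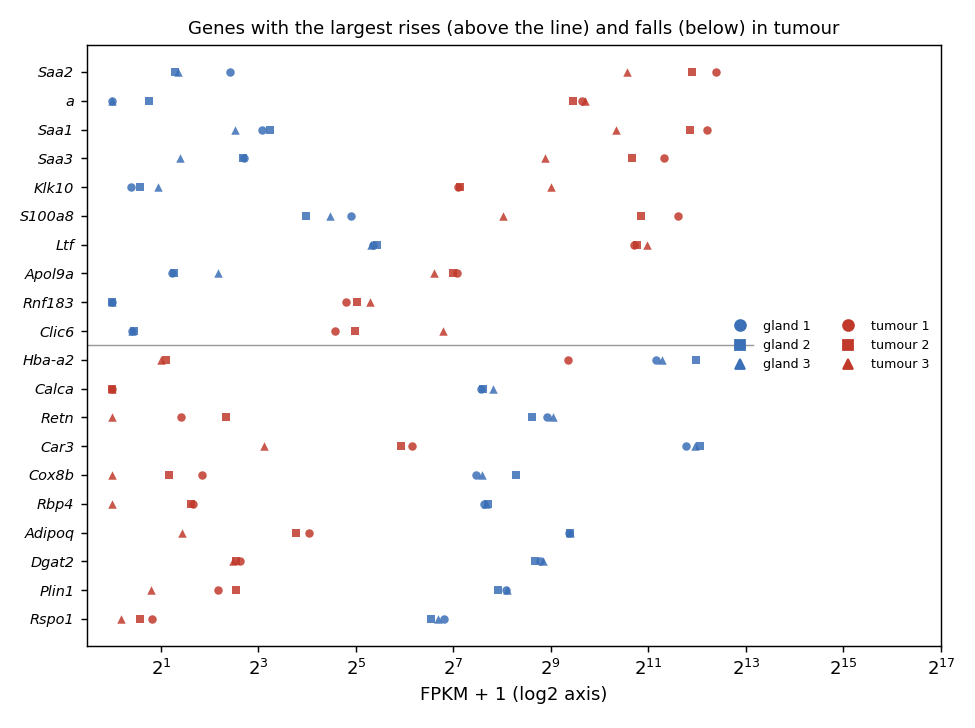
FPKM + 1 on a log2 axis in each of the 6 libraries (points: glands blue, tumours red) for the 10 genes with the largest rises, above the line, and the 10 with the largest falls, below it. The tumour libraries of Saa2 sit between 1518 and 5373 FPKM, above gland values of at most 4.32, and the tumour values of Adipoq between 1.72 and 15.4 FPKM, below gland values of at least 661.

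Of 13364 genes with a mean of at least 1 FPKM, 6023 passed an adjusted p of 0.05 in limma, 2933 of them higher and 3090 lower in the tumours, and 1025 and 1942 of these differed at least 2-fold. The 3 values of one group lay beyond the 3 of the other for 58.2% of the tested genes, where chance gives 10%. The median log2 fold change of all tested genes was 0.008, and 0.119 under quantile normalization. The balance of directions depended on the scaling. Quantile normalization gave 3664 genes higher and 2622 lower, and a common sum per library gave 2355 higher and 3520 lower. Glands 1 and 3 had high lymph node genes, and a fit without both, chosen after seeing the data, called 1858 genes, 760 higher and 1098 lower, with 1 gland left. Of the 153 single genes followed in that fit, 110 kept their call or lack of one, 37 lost their call, 1 gained one and 5 that had not passed turned their direction. A call lost in that fit can reflect the 1 gland left as well as a smaller change. Weighting the libraries by their estimated precision gave 10170 genes, in an estimate that did not converge.

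**Figure D2:**
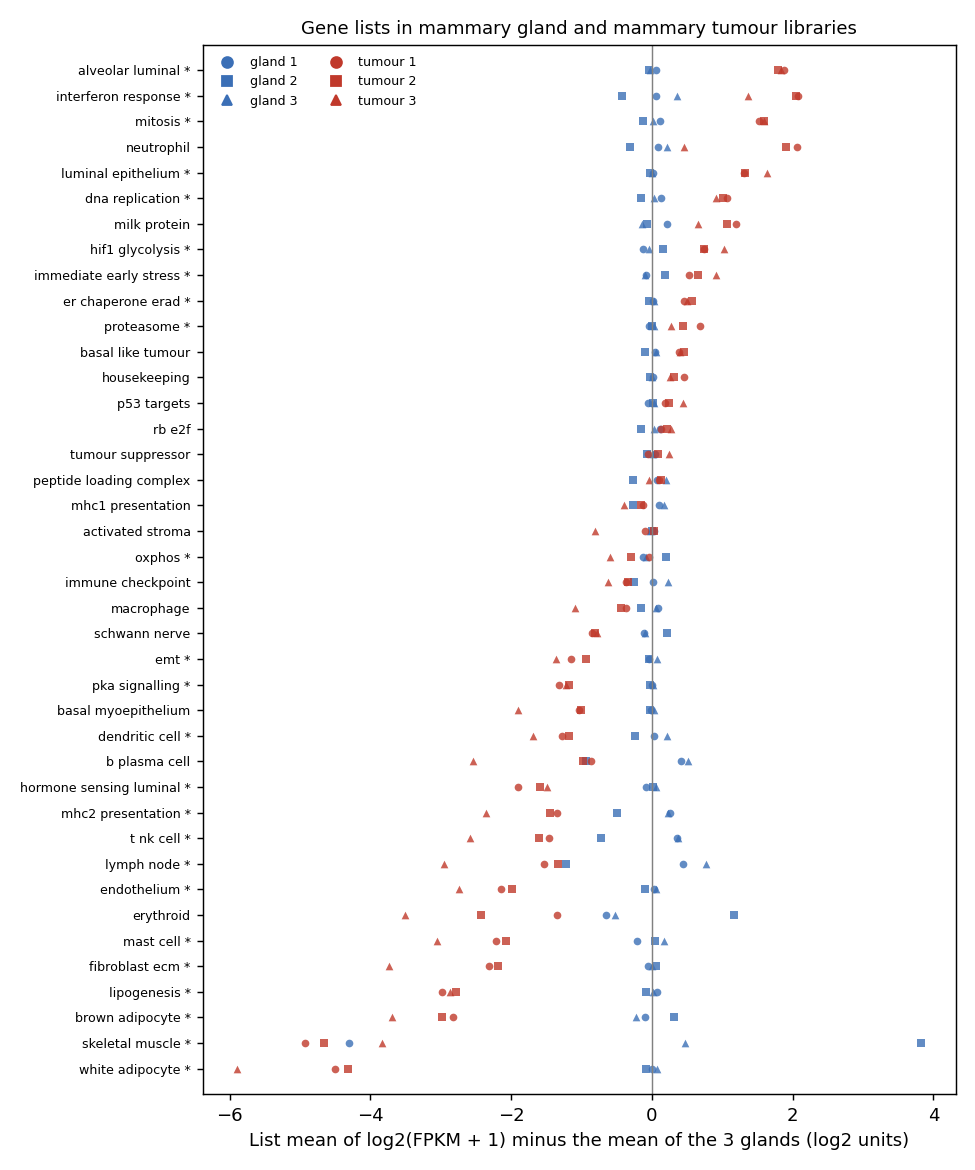
Mean log2(FPKM + 1) of each gene list per library minus the mean of the 3 glands, in log2 units (points: glands blue, tumours red; an asterisk marks an adjusted p under 0.05 in camera). The skeletal muscle list spreads over the glands, with a mean log2(FPKM + 1) of 1.32 in gland 1 and 9.44 in gland 2, and the mitosis list lies higher in each tumour, at 4.86 to 4.93, than in any gland, at 3.203 to 3.44.

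Genes of cell division rose together. All 20 tested genes of the mitosis list were higher in the tumours (median log2 fold change 1.55, camera, adjusted p = 1.2e-11), among them cyclin B1 (Ccnb1, 8.68 to 38.8 FPKM, 2.04), the ubiquitin-conjugating enzyme Ube2c (1.97), and the mitotic kinases Aurka (2.01) and Plk1 (2.08), with SEs of 0.10 to 0.13. The mitosis list had adjusted p = 0.369 with an estimated correlation. All 20 genes of the DNA replication list were higher too (median 0.95, adjusted p = 5.7e-08), such as the ribonucleotide reductase subunits Rrm2 (12.7 to 64.7 FPKM, 2.27, SE 0.10) and Rrm1 (1.10) and the helicase subunit Mcm6 (1.17). The DNA replication list had adjusted p = 0.414 with an estimated correlation. Counts of list members adjusted over the list alone equalled those over all genes, here and below, except where another number is given.

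Markers of luminal and alveolar epithelium rose, and markers of hormone-sensing epithelium fell. Of 14 tested luminal epithelium genes 13 were higher and 1 did not pass (median 1.28, adjusted p = 9.3e-08): the tight junction gene Cldn4 rose from 27.8 ± 2.19 to 191 ± 27.3 FPKM (2.73, SE 0.13) and the mucin gene Muc1 by 2.30. The luminal epithelium list had adjusted p = 0.369 with an estimated correlation. Keratin 8 (Krt8) rose from 228 ± 3.98 to 869 ± 31.1 (1.92, SE 0.10). Of 8 alveolar luminal genes 5 were higher and 3 did not pass (median 1.23, adjusted p = 0.00666). The alveolar luminal list had adjusted p = 0.41 with an estimated correlation. Beside Ltf these included lipocalin 2 (Lcn2, 281 ± 17.6 to 7674 ± 241 FPKM, 4.77), kappa casein (Csn3, 2.64) and Elf5, the transcription factor of alveolar cells (1.27, SE 0.14). The milk protein genes went both ways, with 5 of 9 higher, 2 lower and 2 not passing, and the list did not pass (adjusted p = 0.058). Alpha-lactalbumin (Lalba) rose from 55.96 ± 12.9 to 1629.6 ± 301 FPKM (4.85). The casein gene Csn1s2a fell from 5221 ± 654 to 469 ± 237 (-3.64). It lost its call without glands 1 and 3, which left 1 gland, at a log2 fold change of -3.63. Beta casein (Csn2), at 9106 ± 852 FPKM in the glands and 9749 ± 1566 in the tumours, did not pass (adjusted p = 0.769), with a log2 fold change of 0.09. The log2 fold change of Csn2 was -0.00202 without tumour 1. The milk protein list passed without gland 1 (adjusted p = 0.036), with no filter (adjusted p = 0.0372), at a common sum (adjusted p = 0.0182) and in fry (adjusted p = 0.00422, range 0.00422 to 0.516 over its alternatives).

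Of 9 hormone-sensing luminal genes 6 were lower and 3 did not pass (median -2.17, adjusted p = 0.00276). The hormone sensing luminal list had adjusted p = 0.41 with an estimated correlation. The RANK ligand gene Tnfsf11 fell from 16.9 ± 2.39 to 0.302 ± 0.289 FPKM (-3.80, SE 0.21) and Wnt4 by 2.63. The oestrogen receptor gene Esr1 fell from 8.69 ± 0.805 to 1.51 ± 0.532 (-1.97, SE 0.18) and its partner factor Foxa1 by 2.20. Foxa1 lost its call without glands 1 and 3, which left 1 gland, at a log2 fold change of -2.27. The basal and myoepithelial list did not pass (adjusted p = 0.0845), with 6 of 13 genes lower, 2 higher and 5 not passing, and 3 higher when adjusted over the list alone. Its call was gained without tumour 1 (adjusted p = 0.0499), at a mean of at least 5 FPKM (adjusted p = 0.0305), in fry (adjusted p = 0.0269) and under quantile normalization (adjusted p = 0.0194, range 0.0194 to 0.604 over its alternatives). The oxytocin receptor gene Oxtr (28.4 to 1.94 FPKM, -3.34), the smooth muscle actin gene Actg2 (-2.60) and the myosin kinase gene Mylk (-2.95) fell, and Igfbp5 rose (1.46). The call of Mylk was lost without glands 1 and 3 (adjusted p = 0.0534, range 2.1e-07 to 0.0534 over its alternatives). Of 10 tested genes of the basal-like tumour list 7 were higher, 1 was lower and 2 did not pass (adjusted p = 0.0572). The keratins Krt6a (2.51) and Krt16 (1.82) and the factor Foxc1 (1.62) rose, the last without a call when glands 1 and 3 were left out (adjusted p = 0.0784, range 5.4e-07 to 0.0784 over its alternatives). The HLH factor Id4 fell from 21.1 ± 0.776 to 0.976 ± 0.606 FPKM (-3.53). That list passed without gland 1 (adjusted p = 0.0401), gland 2 (adjusted p = 0.035), gland 3 (adjusted p = 0.0315) or tumour 1 (adjusted p = 0.0484). It also passed with no filter (adjusted p = 0.0293), at a common sum (adjusted p = 0.017), without glands 1 and 3 (adjusted p = 0.0248) and in fry (adjusted p = 0.00529, range 0.00529 to 0.454 over its alternatives). Of the epidermis list only 3 genes were tested, too few for a set test, and Sprr1a rose (2.43, SE 0.43) while 2 did not pass. Its call was lost without glands 1 and 3 (adjusted p = 0.0894, range 1.4e-05 to 0.0894 over its alternatives).

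Interferon-induced genes rose in the tumours. Of 21 genes of the interferon response list 15 were higher, 3 lower and 3 not passing, and 16 higher when adjusted over the list alone (median 2.68, adjusted p = 2.5e-05). The interferon response list had adjusted p = 0.491 with an estimated correlation. The antiviral oligoadenylate synthetase genes Oas2 (2.14 ± 0.528 to 96.3 ± 15.4 FPKM, 4.96, SE 0.17) and Oas1a (3.79), the interferon regulatory factor Irf7 (17.5 ± 4.198 to 264 ± 50.1, 3.85) and Ifi44 (3.36) had the smallest p. The list mean was 5.91, 5.89 and 5.21 in tumours 1 to 3 and 3.89, 3.41 and 4.201 in glands 1 to 3.

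Proteasome genes rose by smaller amounts: 17 of 26 were higher, 9 did not pass, and 18 were higher when adjusted over the list alone (median 0.48, adjusted p = 2.5e-05). The proteasome list had adjusted p = 0.468 with an estimated correlation. The regulatory particle genes Psmd12 (47.6 ± 1.84 to 78.3 ± 1.98 FPKM, 0.71), Psmd1 (0.64) and Psmd2 (0.61) were among them. The calls of Psmd1 and Psmd2 were lost without glands 1 and 3 (adjusted p = 0.084 and 0.105, the highest over their alternatives). Of 18 genes of the endoplasmic reticulum (ER) chaperone and degradation list 11 were higher, 1 lower and 6 not passing, and 13 higher over the list alone (median 0.49, adjusted p = 7.1e-04), such as the unfolded protein response factor Xbp1 (139 ± 5.03 to 553 ± 35.2 FPKM, 1.98), Ubxn4 (0.98), the chaperone BiP (Hspa5, 0.96) and Atf4 (0.71). The ER chaperone list had adjusted p = 0.369 with an estimated correlation. In the hypoxia and glycolysis list 15 of 22 genes were higher, 3 lower and 4 not passing (median 1.17, adjusted p = 6.4e-04). The hypoxia and glycolysis list had adjusted p = 0.454 with an estimated correlation. The glucose transporter Slc2a1 rose from 20.8 ± 3.50 to 68.7 ± 6.79 FPKM (1.69), the glycolytic enzyme Pgam1 by 1.26 and the carbonic anhydrase Car9 by 2.26. Immediate early and stress genes were higher in 9 of 13 cases, lower in 2 and not passing in 2, and 10 higher over the list alone (median 0.58, adjusted p = 0.0137), a call lost under quantile normalization (adjusted p = 0.0636) and without glands 1 and 3 (adjusted p = 0.0884, range 0.00319 to 0.468 over its alternatives). The immediate early list had adjusted p = 0.468 with an estimated correlation. Ier3 rose by 3.18 and Atf3 by 1.65, and the phosphatase gene Dusp1 fell by 2.02. Oxidative phosphorylation genes were lower in 7 of 21 cases, with 14 not passing and 1 lower over the list alone (median -0.17, adjusted p = 0.0473), and the call was lost without gland 2 (adjusted p = 0.204), tumour 2 (adjusted p = 0.0782) or tumour 3 (adjusted p = 0.259), with no filter (adjusted p = 0.0606), under median-of-ratios scaling (adjusted p = 0.0779), with array weights (adjusted p = 0.0706, and 0.11 gene by gene) and in fry (adjusted p = 0.232, range 1.9e-04 to 0.685 over its alternatives). The oxidative phosphorylation list had adjusted p = 0.685 with an estimated correlation. Sdha fell from 173 ± 20.6 to 98.4 ± 5.98 FPKM (-0.80) and Ndufv1 by 0.51, the latter without a call when glands 1 and 3 were left out (adjusted p = 0.0612, range 6.5e-04 to 0.0612 over its alternatives). The list mean was 7.89, 8.22 and 7.93 in glands 1 to 3, highest in gland 2, which also had the highest skeletal muscle list mean, and Sdha stood at 162, 196 and 160 FPKM in these glands.

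Fat cell and lipid synthesis genes fell. White adipocyte genes were lower in 15 of 16 cases (median -4.89, adjusted p = 1.6e-09): the lipases Lipe (183 ± 13.4 to 14.7 ± 1.78 FPKM, -3.55) and Pnpla2 (-2.82) and leptin (Lep, 47.8 ± 1.29 to 0.688 ± 0.530, -4.91). The white adipocyte list had adjusted p = 0.454 with an estimated correlation. The adipogenic factor Cebpa, at 21.6 ± 1.70 FPKM in the glands and 18.9 ± 4.66 in the tumours, did not pass (-0.21, adjusted p = 0.408). The log2 fold change of Cebpa was 0.00331 without tumour 3. Brown adipocyte genes were lower in 7 of 8 cases (median -2.95, adjusted p = 1.7e-04), including the uncoupling protein Ucp1 (103 ± 18.001 to 0.757 ± 0.672 FPKM, -5.95) and Cidea (-3.83). The brown adipocyte list had adjusted p = 0.454 with an estimated correlation. Of 12 lipogenesis genes 11 were lower and 1 did not pass (median -2.91, adjusted p = 9.1e-08), such as acetyl-CoA carboxylase (Acaca, -3.44), Elovl6 (-3.75) and the desaturase Scd1 (4403 ± 95.3 to 232 ± 57.9 FPKM, -4.28). The lipogenesis list had adjusted p = 0.274 with an estimated correlation. In the protein kinase A (PKA) signalling list 13 of 19 genes were lower and 6 did not pass, with 1 higher over the list alone (median -0.93, adjusted p = 3.7e-04). The PKA signalling list had adjusted p = 0.274 with an estimated correlation. The members with the smallest p were the phosphodiesterase Pde3b (-3.47), the regulatory subunit Prkar2b (71.5 ± 2.07 to 6.40 ± 1.64 FPKM, -3.32) and the beta-3 adrenergic receptor of fat cells, Adrb3 (-4.83). The mean of the white adipocyte list was 2.04 in tumour 3 against 3.42 and 3.61 in tumours 1 and 2.

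Skeletal muscle genes set the glands apart from one another. Their list mean was 1.32, 9.44 and 6.08 in glands 1 to 3 and 0.69 to 1.78 in the tumours. The list passed as lower in camera (adjusted p = 0.0137) and not in fry (adjusted p = 0.174), with 1 of 14 genes lower, Myl1, and none when adjusted over the list alone. The skeletal muscle list had adjusted p = 0.604 with an estimated correlation. The call of Myl1 (-5.72, SE 1.53, adjusted p = 0.0211) was lost without gland 3 (adjusted p = 0.0603), tumour 1 (adjusted p = 0.056) or tumour 2, and with tumours 1 and 2 averaged (adjusted p = 0.0705 and 0.0617, range 1.6e-04 to 0.0705 over its alternatives). The log2 fold change of Myl1 was -7.36 without gland 1 and -4.03 without gland 2. Muscle actin, Acta1, stood at 3.63, 3831 and 346 FPKM in glands 1 to 3 (adjusted p = 0.0881). Acta1 passed without gland 1 (adjusted p = 0.0035), without glands 1 and 3 (adjusted p = 0.0154) and with array weights (adjusted p = 0.00262, range 0.00262 to 0.207 over its alternatives).

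Fibroblast and endothelial genes fell. All 15 fibroblast and matrix genes were lower (median -2.62, adjusted p = 2.4e-06), among them gelsolin (Gsn, 954 ± 45.5 to 44.8 ± 15.4 FPKM, -4.45), Pi16 (-3.24) and the receptor Pdgfra (-3.38, SE 0.31). The fibroblast list had adjusted p = 0.468 with an estimated correlation. All 11 endothelial genes were lower (median -2.28, adjusted p = 2.7e-06), such as the receptors Kdr (18.97 ± 1.78 to 2.44 ± 0.623 FPKM, -2.55) and Tek (-2.44) and von Willebrand factor (Vwf, -2.46). The endothelium list had adjusted p = 0.434 with an estimated correlation. In the epithelial-mesenchymal transition list 8 of 10 genes were lower, 1 higher and 1 not passing (median -1.39, adjusted p = 0.00276), with falls of the transcription factors Zeb2 (-2.33), Twist1 (13.7 ± 0.278 to 1.10 ± 0.487 FPKM, -2.83) and Zeb1 (-2.46), which fibroblasts also express. The epithelial-mesenchymal transition list had adjusted p = 0.468 with an estimated correlation. The list means of tumour 3 lay below those of the other tumours, at 3.05 against 4.47 and 4.600 for fibroblasts and 1.86 against 2.46 and 2.61 for endothelium. The activated stroma list did not pass (adjusted p = 0.615), with 6 of 15 genes higher, 7 lower and 2 not passing. Mmp9 (-3.01), Fap (-2.61) and Mmp2 (-2.74) fell and the collagenase Mmp13 rose (1.62). The Schwann cell and nerve list (adjusted p = 0.146, and 0.00344 in fry) had 5 of 8 genes lower, 2 higher and 1 not passing. It held falls of the myelin genes Pmp22 (-2.69) and Mbp (-1.46) and a rise of Sox10 (60.03 ± 3.11 to 167 ± 55.5 FPKM, 1.41), which mammary epithelium also expresses. The call of Sox10 was lost without glands 1 and 3 (adjusted p = 0.0936, range 1.4e-06 to 0.0936 over its alternatives). Of 6 erythroid genes 3 were lower and 3 did not pass (adjusted p = 0.0933). The haem synthesis gene Alas2 fell by 1.94. Hbb-bs, at 463, 499.9 and 3.53 FPKM in tumours 1 to 3 and 2588 ± 1108 in the glands, did not pass (adjusted p = 0.0688). Hbb-bs passed without tumour 3 (adjusted p = 0.00181), with the replicate block (adjusted p = 0.0465), with array weights (adjusted p = 0.00724) and gene by gene (adjusted p = 0.0322, range 0.00181 to 0.332 over its alternatives). The erythroid list passed without tumour 1 (adjusted p = 0.0452), in fry (adjusted p = 0.0304) and without glands 1 and 3 (adjusted p = 0.0245, range 0.0245 to 0.468 over its alternatives).

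The T and natural killer (NK) cell, lymph node, MHC class II, dendritic cell and mast cell lists passed as lower. Of 20 tested T and NK cell genes 18 were lower and 2 did not pass, and all 20 were lower when adjusted over the list alone (median -2.17, adjusted p = 6.9e-06). The T and NK cell list had adjusted p = 0.48 with an estimated correlation. The NK receptor Ncr1 fell from 4.45 ± 1.16 to 0.283 ± 0.246 FPKM (-2.08, SE 0.24) and granzyme A (Gzma) from 9.62 ± 1.36 to 0.902 ± 1.09 (-2.63, SE 0.39). The receptor gene Klrd1 fell by 2.25. Without the high lymph node glands 1 and 3 the calls of Gzma (-2.43, adjusted p = 0.104) and Klrd1 (-1.72, adjusted p = 0.0927) were lost, each the highest adjusted p over its alternatives. Tbx21, the T-bet gene, stood at 3.22, 1.58 and 2.24 FPKM in glands 1 to 3 and was listed at 0 in the tumours (adjusted p = 0.00128). The T cell receptor subunit Cd3d, at 11.1 ± 6.32 FPKM in the glands and 2.44 ± 2.19 in the tumours, did not pass over all genes (adjusted p = 0.0665). Cd3d passed without gland 2 (adjusted p = 0.0363), with array weights (adjusted p = 0.00165) and gene by gene (adjusted p = 0.0138, range 0.00165 to 0.648 over its alternatives). The list mean was 3.36, 2.27 and 3.37 in glands 1 to 3 and 1.53, 1.39 and 0.42 in tumours 1 to 3. Lymph node genes were lowest in gland 2 among the glands too, with list means of 3.597, 1.93 and 3.92, against 1.62, 1.82 and 0.201 in the tumours. Of these 3 of 9 were lower, 2 when adjusted over the list alone, and 6 did not pass (median -2.04, adjusted p = 0.0167), a call lost without tumour 3 (adjusted p = 0.0562, range 0.00154 to 0.568 over its alternatives) and without glands 1 and 3 (adjusted p = 0.132). The lymph node list had adjusted p = 0.568 with an estimated correlation. The vascular addressin gene Madcam1 fell from 14.7 ± 2.70 to 0.235 ± 0.247 FPKM (-3.67). The call of the lymphotoxin gene Ltb (-2.10, adjusted p = 0.0428) was lost without gland 1 (adjusted p = 0.116), gland 3 (adjusted p = 0.13), tumour 1 (adjusted p = 0.0572) or tumour 3 (-1.41, adjusted p = 0.0623). It was also lost with the replicate block (adjusted p = 0.0687), a pseudocount of 0.1 (adjusted p = 0.0502), no filter (adjusted p = 0.0616), tumours 1 and 2 averaged (adjusted p = 0.0502) and glands 1 and 3 left out (adjusted p = 0.546, range 5.1e-04 to 0.546 over its alternatives). The follicle chemokine Cxcl13, at 43.2 ± 28.3 FPKM in the glands and 6.87 ± 5.88 in the tumours, did not pass (adjusted p = 0.0683). Cxcl13 passed without gland 2 (adjusted p = 0.0403), with array weights (adjusted p = 6.5e-04) and gene by gene (adjusted p = 0.0082, range 6.5e-04 to 0.647 over its alternatives).

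Of 12 MHC class II presentation genes 10 were lower and 2 did not pass (median -2.01, adjusted p = 0.00127). The MHC class II list had adjusted p = 0.491 with an estimated correlation. The peptide exchange genes H2-DMb1 (-1.95) and H2-DMa (-2.23), the class II chain H2-Eb1 (-2.44) and the invariant chain Cd74 (1512 ± 361 to 300.5 ± 105 FPKM, -2.37, SE 0.32) fell. All 4 calls were lost without glands 1 and 3, at -1.52 for H2-DMb1 (adjusted p = 0.0512), -1.86 for H2-DMa (adjusted p = 0.0767), -2.12 for H2-Eb1 (adjusted p = 0.0849) and -1.96 for Cd74 (adjusted p = 0.085), each the highest adjusted p over its alternatives. The protease gene Ctss, at 172 ± 31.7 FPKM in the glands and 170.2 ± 59.2 in the tumours, did not pass (-0.06, adjusted p = 0.88). The log2 fold change of Ctss was 0.011 without gland 1, 0.0277 without gland 3 and 0.25 without tumour 3. Dendritic cell genes were lower in 5 of 6 cases (median -1.54, adjusted p = 0.0165), including Zbtb46 (5.07 ± 0.341 to 0.418 ± 0.265 FPKM, -2.11) and Cd209a (-2.45). The dendritic cell list had adjusted p = 0.468 with an estimated correlation. Mast cell genes were lower in 4 of 5 cases (median -3.71, adjusted p = 0.00276), including the proteases Cpa3 (19.99 ± 2.77 to 0.697 ± 0.723 FPKM, -3.71) and Cma1 (-4.11). The mast cell list had adjusted p = 0.468 with an estimated correlation. The dendritic cell list (adjusted p = 0.00177 to 0.468 over its alternatives) lost its call without glands 1 and 3, which left 1 gland. Cd209a lost its call there too, at a log2 fold change of -2.76.

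B and plasma cell genes did not pass as a list (adjusted p = 0.0979): 4 of 11 were lower, 1 higher and 6 not passing, and 6 were lower when adjusted over the list alone. The immunoglobulin joining chain Jchain fell from 94.02 ± 8.23 to 10.5 ± 7.53 FPKM (-3.35, or -2.64 without tumour 3), and the member that rose was Xbp1, which epithelial cells also express. The call of Jchain was lost without glands 1 and 3, which left 1 gland, at a log2 fold change of -3.20. Cd79a, at 30.8 ± 21.5 FPKM in the glands and 8.71 ± 7.11 in the tumours, did not pass (adjusted p = 0.193), and passed with array weights (adjusted p = 0.00913, range 0.00913 to 0.97 over its alternatives). The list passed without gland 2 (adjusted p = 0.0144), with array weights (adjusted p = 0.0334) and gene by gene (adjusted p = 0.0487, range 0.0144 to 0.678 over its alternatives). Macrophage genes went both ways, with 8 of 15 lower, 2 higher and 5 not passing, and 3 higher over the list alone (adjusted p = 0.0845). Arginase 1 (Arg1) rose from 21.99 ± 1.996 to 139 ± 13.8 FPKM (2.61, SE 0.12) and Cd14 by 1.85. The scavenger receptor Cd163 fell by 1.56 and the growth factor receptor Csf1r by 1.14. Csf1r lost its call without glands 1 and 3, which left 1 gland, at a log2 fold change of -0.97. The macrophage list passed without tumour 1 (adjusted p = 0.0404), with tumours 1 and 2 averaged (adjusted p = 0.0484) and under quantile normalization (adjusted p = 0.0248, range 0.0248 to 0.663 over its alternatives). Of 9 neutrophil genes Ltf and S100a8 were higher and 7 did not pass (adjusted p = 0.14), among them S100a9, the partner of S100a8, at 10.2 ± 2.47 FPKM in the glands and 55.03, 39.2 and 9.15 in tumours 1 to 3 (adjusted p = 0.105). S100a9 passed without tumour 3 (adjusted p = 7.7e-04), with array weights (adjusted p = 5.7e-05) and gene by gene (adjusted p = 0.00201, range 5.7e-05 to 0.333 over its alternatives). The neutrophil list passed without tumour 3 (adjusted p = 0.00513), with no filter (adjusted p = 0.0257), in fry (adjusted p = 0.0092), with array weights (adjusted p = 0.0334) and gene by gene (adjusted p = 0.0409, range 0.00513 to 0.604 over its alternatives). Of 6 tested immune checkpoint genes 3 were lower, 1 higher and 2 not passing (adjusted p = 0.551). The PD-L1 gene Cd274 fell from 7.56 ± 3.15 to 1.14 ± 0.516 FPKM (-1.96, SE 0.32) and Lag3 by 1.09, and the B7 family ligand Vtcn1 rose from 4.89 ± 0.252 to 11.2 ± 0.359 (1.05, SE 0.11). The calls of Cd274 (-1.32, adjusted p = 0.0766) and Lag3 (-0.88, adjusted p = 0.152) were lost without glands 1 and 3, each the highest adjusted p over its alternatives.

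Of the 40 lists tested, 24 passed in camera, 9 higher and 15 lower, with a preset correlation of 0.01 between genes. None passed with an estimated correlation, where 5 had an unadjusted p under 0.05, and fry gave 30, 14 higher and 16 lower, of which 22 were also called by camera. Camera at the preset correlation also called 8 to 23 lists in the other splits of the 6 libraries into 3 and 3, so its calls alone are weak evidence. Among the members that moved against their list, chosen after their values were seen, were Irf1, Gbp2 and Cxcl9, lower in the interferon list, Derl1, lower in the ER list, and Hk2, Adm and Bnip3, lower in the hypoxia list.

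The title of the series names loss of antigenicity, and the peptide loading complex, which loads peptides onto MHC class I molecules in the ER, and the tumour suppressors Rb and p53 were followed for that question. Only RNA of whole tissue was measured, so a change of their proteins without a change of RNA would not show here. Of the 7 loading complex genes the chaperone calreticulin (Calr, chromosome 8, 84841850 to 84846934, mm10) rose from 472 ± 49.6 to 802 ± 116 FPKM (mean ± SD, n = 3 each; 0.76, SE 0.16, adjusted p = 0.00775). Its partner Pdia3 (chromosome 2, 121413775 to 121438687) rose from 193 ± 16.04 to 311 ± 25.9 (0.68, SE 0.12, adjusted p = 0.0037). The transporter subunit Tap2 (chromosome 17, 34203527 to 34216321) fell from 91.8 ± 18.02 to 57.1 ± 8.58 FPKM (-0.67, SE 0.18, adjusted p = 0.0223). Its call was lost without gland 1 (-0.60, adjusted p = 0.075), gland 3 (-0.56, adjusted p = 0.0833) or tumour 1 (-0.62, adjusted p = 0.058). The same held with the replicate number as a block (-0.67, adjusted p = 0.0647). The other subunit, Tap1, stood at 77.9 ± 22.2 FPKM in the glands and 68.8 ± 8.68 in the tumours (-0.14, SE 0.23, adjusted p = 0.636). Tapasin (Tapbp) stood at 164 ± 33.7 and 151 ± 12.8 (-0.10, SE 0.17, adjusted p = 0.668) and calnexin (Canx) at 84.2 ± 23.4 and 104 ± 25.2 (0.32, SE 0.24, adjusted p = 0.311). Beta-2 microglobulin (B2m) stood at 4204 ± 432 and 3207 ± 555 (-0.40, SE 0.20, adjusted p = 0.144). None of these 4 passed. Tap1 had a log2 fold change of 0.0388 without gland 3 and passed as lower with array weights (adjusted p = 0.0491, range 9.8e-04 to 0.917 over its alternatives), and Canx stood at -0.13 with array weights. B2m passed as lower without tumour 1 (adjusted p = 0.0471), at a common sum (adjusted p = 0.0331), with the GC and length trend removed (adjusted p = 0.0255), with array weights (adjusted p = 0.00123) and gene by gene (adjusted p = 0.0211, range 7.9e-04 to 0.754 over its alternatives). Rb1 stood at 17.2 ± 1.14 and 19.6 ± 1.37 FPKM (0.18, SE 0.11, adjusted p = 0.21) and the p53 gene Trp53 at 73.8 ± 4.39 and 60.8 ± 6.80 (-0.28, SE 0.11, adjusted p = 0.0875). Neither passed. Trp53 passed without tumour 3 (adjusted p = 0.0205), with the GC and length trend removed (adjusted p = 0.0313) and with array weights (adjusted p = 1.4e-04, range 2.7e-05 to 0.549 over its alternatives). Rb1 passed with array weights (adjusted p = 0.0014, range 1.7e-04 to 0.551 over its alternatives), in an estimate that did not converge, and with array weights gene by gene (adjusted p = 0.037), as did Trp53 (adjusted p = 0.00385). The lowest adjusted p in the ranges of Tap1, B2m, Trp53 and Rb1 came from the fit relative to the luminal epithelium list. That reference rose in the tumours and moves every gene down, and Rb1 stood at -1.24 there. Those low values thus do not bear on the changes given here. Trim71, a ubiquitin ligase gene, was listed at 0 in all glands and in tumours 1 and 2 and at 0.0757 FPKM in tumour 3.

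**Figure D3:**
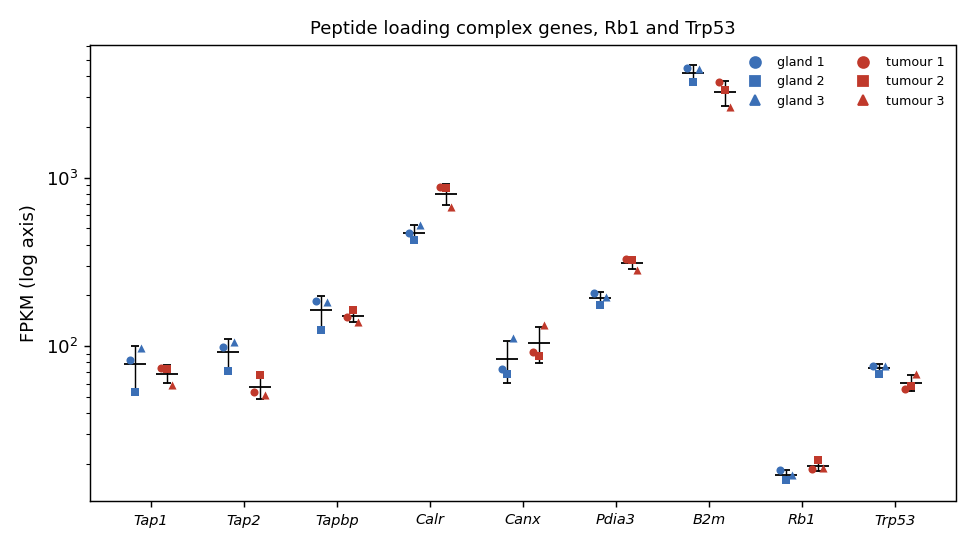
FPKM on a log axis in each library for the peptide loading complex genes, Rb1 and Trp53 (points: glands blue, tumours red; dashes and bars: mean ± SD of 3 libraries). Calr lies between 668 and 875 FPKM in the tumours against 424 to 523 in the glands, and the values of Tap1, Tapbp, Canx and B2m overlap between the groups.

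The 3 tumours lay above all 3 glands for Calr, Pdia3 and Rb1 and below them for Tap2 and Trp53, and 2-sided exact permutation tests of these 5 genes gave p = 0.1, the smallest that 3 samples against 3 allow. Exact permutation tests of Tap1, Tapbp, Canx and B2m gave p = 0.6, p = 0.7, p = 0.4 and p = 0.2. The loading complex list did not pass (camera, adjusted p = 0.729): camera put it higher and its mean log2 fold change was 0.06, while its median was -0.10. Camera put it lower without gland 2 (adjusted p = 0.798) and under quantile normalization (adjusted p = 0.724, range 0.236 to 0.98 over its alternatives). Of the 18 genes of the wider MHC class I list 2 were higher, 5 lower and 11 not passing (median -0.15, adjusted p = 0.253), and under quantile normalization the list passed as lower (adjusted p = 0.0248, range 0.0248 to 0.854 over its alternatives). The immunoproteasome subunit Psmb10 fell from 79.3 ± 18.8 to 37.2 ± 8.95 FPKM (-1.07, SE 0.23, adjusted p = 0.00984), a call lost without glands 1 and 3 (adjusted p = 0.236, range 1.0e-05 to 0.236 over its alternatives). The peptide-trimming gene Erap1 fell by 0.53 (adjusted p = 0.0133), a call lost without gland 1 (adjusted p = 0.0535), gland 3 (adjusted p = 0.0582) or both (adjusted p = 0.245, range 2.7e-05 to 0.245 over its alternatives). The class I heavy chain H2-D1, at 1288 ± 157 FPKM in the glands and 1012 ± 144 in the tumours, did not pass (adjusted p = 0.134). H2-D1 passed as lower under quantile normalization (-0.43, adjusted p = 0.0403), at a common sum (adjusted p = 0.0498), with array weights (adjusted p = 0.00655) and gene by gene (adjusted p = 0.0432, range 0.00655 to 0.768 over its alternatives).

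Values relative to the luminal epithelium list or to the leukocyte gene Ptprc shift every gene by the change of that reference. The luminal list had a mean log2 fold change of 1.42, and Ptprc fell by 1.70 (adjusted p = 0.00662). Relative to the luminal list Calr stood at -0.66 and Tap1 at -1.56, and relative to Ptprc Tap1 stood at 1.56 and Tap2 at 1.04. With glands 1 and 3 left out, which left 1 gland, none of the 9 tested genes passed. In that fit Calr stood at 0.91 (adjusted p = 0.112, range 2.2e-06 to 0.112 over its alternatives) and Pdia3 at 0.82 (adjusted p = 0.0694, range 5.2e-06 to 0.0694 over its alternatives). Tap2 stood at -0.33 (adjusted p = 0.367), Tap1 at 0.34 and Tapbp at 0.27.

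In the Rb and E2F list 7 of 16 genes were higher, 3 lower and 6 not passing (median 0.38, adjusted p = 0.15): the kinase inhibitor gene Cdkn2a rose from 1.46 ± 1.12 to 13.7 ± 1.18 FPKM (2.67) and cyclin E1 (Ccne1) by 1.37. Cyclin D2 (Ccnd2) fell from 29.8 ± 3.88 to 2.84 ± 0.726 (-3.01) and Cdkn2c by 1.10. Without glands 1 and 3, which left 1 gland, the calls of Ccne1 and Cdkn2c were lost, at log2 fold changes of 1.51 and -0.97. Cyclin D1 (Ccnd1), at 54.9 ± 5.67 and 79.2 ± 35.2 FPKM, did not pass (adjusted p = 0.238). Of 16 p53 target genes 7 were higher, 2 lower and 7 not passing, and 3 lower over the list alone (median 0.43, adjusted p = 0.26, and 0.0272 in fry). Perp rose by 1.75 and the p21 gene Cdkn1a from 16.7 ± 1.60 to 82.7 ± 31.8 FPKM (2.18, SE 0.25), and Sesn1 fell by 1.45 and Phlda3 by 1.16. The calls of Cdkn1a and Phlda3 were lost without glands 1 and 3, at log2 fold changes of 2.04 and -1.10. Of 11 tumour suppressor genes 1 was higher, 2 lower and 8 not passing, and 1 lower over the list alone (adjusted p = 0.796), with camera direction higher, or lower without tumour 3 (adjusted p = 0.859, range 0.468 to 0.912 over its alternatives). Brca1 rose by 0.80, a call lost without glands 1 and 3, where its log2 fold change was 1.03. Smad4 (-0.37, adjusted p = 0.0398) lost its call without gland 1 (adjusted p = 0.115), gland 2 (adjusted p = 0.069), gland 3 (adjusted p = 0.132), tumour 1 (adjusted p = 0.0846) or tumour 2 (adjusted p = 0.124). It was also lost with the replicate block (adjusted p = 0.0875), at a common sum (adjusted p = 0.0706), with tumours 1 and 2 averaged (adjusted p = 0.1) and without glands 1 and 3 (adjusted p = 0.363, range 4.5e-05 to 0.363 over its alternatives). The housekeeping list did not pass (adjusted p = 0.102), with 5 of 14 genes higher, 1 lower and 8 not passing. It passed with no filter (adjusted p = 0.0498) and in fry (adjusted p = 0.0269, range 0.0269 to 0.495 over its alternatives). Pgk1, also a gene of glycolysis, rose by 1.56 and Ywhaz by 0.70. The call of Pgk1 was lost without glands 1 and 3 (adjusted p = 0.0522, range 2.0e-06 to 0.0522 over its alternatives). The elongation factor Eef1a1 stood at 4672 ± 328 FPKM in the glands and 4394 ± 249 in the tumours (adjusted p = 0.697).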

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

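The tests with a common sum, with tumours 1 and 2 averaged, without glands 1 and 3, with the GC and length trend removed and with array weights gene by gene were chosen only after the results were seen. Over all alternatives but the 2 relative to a reference, 2634 values of named genes and 676 of lists kept their direction and their side of the threshold. 68 and 38 lost their call, 34 and 35 gained one, and 17 and 6 turned their direction. Leaving out each library in turn gave 4217 to 6402 genes (2043 to 3094 higher, 2174 to 3308 lower), 23 to 28 lists and 2 to 4 study genes, with adjusted p = 0.0538 to 0.610 for the MHC class I list and 0.515 to 0.829 for the peptide loading complex list. Other counts were 5971 genes with a pseudocount of 0.1, 6757 with no filter (2954 higher, 3803 lower) and 4328 at a mean of at least 5 FPKM (2464 higher, 1864 lower). Quantile normalization gave 6286 (3664 higher, 2622 lower), median-of-ratios scaling 6107 and a common sum 5875 (2355 higher, 3520 lower). With tumours 1 and 2 averaged 5454 genes passed, and 6675 with the GC and length trend removed (5 study genes). At 2-fold or more 2967 passed (1025 higher, 1942 lower), where fewer genes can pass. The replicate number as a block, which the labels do not give as a pairing, gave 4728 genes (2147 higher, 2581 lower), 24 lists and 2 study genes, Tap2 having lost its call. Array weights gave 10170 genes (5076 higher, 5094 lower), 7 study genes and -0.13 for Canx, in an estimate that did not converge, and gene by gene 8061 genes, 6 study genes and -0.019 for Canx. With an estimated correlation in camera 0 lists passed (5 at an unadjusted p under 0.05, and 30 by fry). Without glands 1 and 3, with fewer samples, 1858 genes (760 higher, 1098 lower) and 0 study genes passed, the MHC class I list turned (adjusted p = 0.854), and Tap1 stood at 0.34, Tapbp at 0.27, Ctss at 0.26, Hba-a1 at -1.13 and Eef1a1 at 0.028. The MHC class I list passed under quantile normalization (adjusted p = 0.0248). The peptide loading complex list turned under quantile normalization (adjusted p = 0.724), without gland 2 (adjusted p = 0.798) and with array weights (adjusted p = 0.897), and the tumour suppressor list at a mean of at least 5 FPKM (adjusted p = 0.630) and without tumour 3 (adjusted p = 0.859), with 0.468 to 0.862 over the fits without 1 library. Directions of genes that had not passed turned for 5 genes without 1 library. Ctss ranged from -0.28 to 0.25 (0.011 without gland 1, 0.028 without gland 3, 0.25 without tumour 3). Hba-a1 ranged from -0.78 (without tumour 2) to 1.93 (without tumour 1), with -0.023 without gland 1, -0.19 without gland 3 and -0.45 without tumour 3. Tap1 ranged from -0.39 to 0.039 (without gland 3), Csn2 from -0.0020 (without tumour 1) to 0.23 and Cebpa from -0.32 to 0.0033 (without tumour 3). Relative to the luminal epithelium list 9 study genes passed, with Calr at -0.66, Canx at -1.10, Pdia3 at -0.74 and Rb1 at -1.24, and relative to Ptprc 9 passed, with Tap1 at 1.56, Tap2 at 1.04, Tapbp at 1.60, B2m at 1.30 and Trp53 at 1.42, where the reference shifts all genes alike (by a mean of -1.42 for the luminal list and 1.70 for Ptprc). Apart from fewer genes, fewer samples and the references, the cause was not tested. Depth limits genes under 1 FPKM most, and absolute depth is unknown.

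The real split of the 6 libraries gave 6023 genes and 24 lists. The other splits gave 0 to 2 genes and 8 to 23 lists, so that 1 split reached each real value. At the preset correlation camera thus called many lists under every other grouping, and its count of lists hardly sets the real split apart. There are 10 splits, too few for a share under 0.05.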

Other observations

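The tests on the chromosome 17 block, on a copy gain of chromosome 1, on chromosome 1 without all genes lower in tumour 3, and on the muscle and lymph node genes of the glands were chosen only after the results were seen. Neighbouring genes moved together in several places, described here by the median log2 fold change of 11 neighbouring tested genes, all chosen after their values were seen. A run on chromosome 5 (mm10, 120589016 to 120907521) that holds antiviral Oas genes stood at 2.05. One on chromosome 3 (90526856 to 92485895), from S100a14 to Sprr1a, genes of epithelial differentiation, stood at 1.87. One on chromosome 6 (48554796 to 48770851) that holds Gimap genes of lymphocytes stood at -2.31, and one on chromosome 8 (3630955 to 4137707), from Stxbp2 to Cd209g, at -2.45. Farsb, a subunit of phenylalanyl-tRNA synthetase chosen after its values were seen, rose from 43.2 ± 3.09 to 883 ± 46.5 FPKM (mean ± SD, n = 3 each), a log2 fold change of 4.32. Among genes of at least 100 FPKM in 5 libraries, 2 lay far below that in the sixth: Rps27 at 8.05 FPKM in gland 1 against at least 1557 elsewhere, and Hbb-bs at 3.53 FPKM in tumour 3 against at least 463.

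On chromosome 17 (mm10, 47368887 to 48539714) 21 tested neighbouring genes, from Mrps10 to Unc5cl, formed a block with cyclin D3 (Ccnd3), Tfeb and Foxp4 among them. They had medians of 2.55 and 2.62 log2 units above the glands in tumours 1 and 2 and 0.36 in tumour 3. Their median for tumours 1 and 2 minus tumour 3 was 2.05, the highest of 12466 runs of that length. The block was chosen after its values were seen, so this rank is no test of it. Of the 21 block genes 81.0% lay over 1 log2 unit above the gland mean in tumours 1 and 2. The block was found by this pattern, so this value does not decide on a copy gain. For tumours 1 and 2 minus tumour 3 the highest other run of 21 genes stood at 0.732. The block stood at 2.05 (bootstrap interval 1.88 to 2.31). It was picked as the highest run, so this gap does not decide on another mix of cell types. Among shorter runs, Pet100 to Cd209f on chromosome 8 stood at 1.49 and Lrrc61 to Gimap3 on chromosome 6 at 1.46. At the block, Ubr2 to Tomm6 stood at 2.28 and Prickle4 to Unc5cl at 1.88. Another mix of cell types as the whole cause is argued against by 81 Mrps, Taf, Med, Tomm and Nfy subunits elsewhere. Their median was 0.161 (0.0553 to 0.291), against 1.88 to 2.65 for the 5 in the block. The 10 tested genes on each side had a largest median shift of 0.464. The edges of the block were set after its values were seen, so this does not decide on depth or scaling. Scaling would shift all genes of a library. The 658 tested genes on chromosome 17 had medians of -0.0522 and 0.0357 relative to the glands in tumours 1 and 2, which argues against scaling. A copy gain, a shared origin of tumours 1 and 2 and an effect of the transgene on the region stay open, since DNA was not analysed here and the labels do not say whether these tumours came from 1 animal.

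The median log2 fold change of the 748 tested genes on chromosome 1 was 0.34, against -0.117 to 0.092 on the other chromosomes, and 85% of its 10-Mb bins (17 of 20) were positive in all 3 tumours, against 24.2% elsewhere. Removing the trend with GC content and gene length left 0.339, which argues against such a bias as the whole cause. Its bootstrap interval, 0.271 to 0.405, came from resampling genes and measures no spread between tumours. Genes over 0.5 log2 units lower in tumour 3 than in tumours 1 and 2, as stroma lists were, were also left out. Without the 1345 of them that were lower in the tumours than in the glands, 107.2% of the excess was kept. Without all 1931, whatever their change from the glands, 108% was kept. Epithelial genes stayed in both, and a lower share of non-epithelial cells would raise them, so these values do not decide on that cause. Genes with a mean log2 of at least 4 stood at 0.57 on chromosome 1 and at 0.00617 to 0.238 on the other chromosomes. All chromosomes thus lay above 0 there, so 0.57 is not an excess to set against the 0.585 of a gain from 2 to 3 copies. Over all tested genes the excess of chromosome 1 over the rest was 0.345. A copy gain of chromosome 1 in the tumours is a candidate explanation, found and tested on the same data. A lower share of non-epithelial cells and regulation of many genes on that chromosome stay open.

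The 3 glands differed in muscle and lymph node genes. All 14 tested muscle genes were ordered gland 2, gland 3, gland 1 from high to low, an order taken after the list means were seen, which skeletal muscle in the tissue of glands 2 and 3 could give; Acta1 stood at 3831 FPKM in gland 2. Of the 14 genes 8 had at least 1 FPKM in gland 1 and 10 in some tumour, and 0 are in another list. Lymph node in glands 1 and 3 as the source of the fall of T and NK cell genes cannot be told apart from a lower number of these cells in the tumours, since 1 gland alone had low lymph node genes: its T and NK list mean lay 0.742 above the highest tumour, against an SD of 0.606 between tumours. Of the 10 lymph node genes 9 had at least 1 FPKM in gland 1 and 8 in some tumour, and 0 are in another list.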
